A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 2 samples.

How the data were processed

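Synechococcus elongatus PCC 7942 is a unicellular cyanobacterium that is widely used to study circadian rhythms. RpaA is a response regulator through which its KaiABC clock acts on transcription. RNA came from a wild-type background strain, AMC408, and from a ΔrpaA strain in which a kanamycin resistance cassette disrupts rpaA. Per the labels, each strain was grown in a turbidostat, a vessel that keeps a culture at a set density, at 30 °C and an OD750 of 0.15. The cultures were entrained by 12 h dark periods and then moved to continuous light. They were sampled every 4 h from 24 h to 44 h in the light.

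Equal masses of RNA from the 6 time points were pooled within each strain, so that each pool stands for a time average. The 2 pools were compared on 2 Agilent arrays with 2 colours each. On one array the ΔrpaA pool carried Cy3 and the wild-type pool Cy5, and on the other the dyes were swapped. Per the labels' protocols, 5 µg of total RNA per labelling, with spike-in RNA added, was reverse-transcribed from random primers without amplification.

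The authors deposited 1 log2 ratio of Cy3 over Cy5 per locus for each array, and a second table with the log2 ratio of ΔrpaA over wild type averaged over the arrays. The second table's unit and direction are stated per the file headers, and the averaging formula is stated in the series design text. The scanner software, background correction, within-array normalization, probe filters and the way probes were combined per locus are not given in the sources used here. The median of the deposited log2 ratios was -0.039 on the array with ΔrpaA in Cy3 and -0.12 on the array with ΔrpaA in Cy5, so the columns were not centred on a median of 0. The deposited columns' difference times 0.5 differed from the authors' averaged table by at most 0.0050 at each of the 2723 loci, which is the rounding of a table with 2 decimals. This settles scale, sign and centring of the values relative to the authors' average. Signal intensities were not used here, so the signal behind each ratio is unknown and ratios of dim and bright loci could not be weighed differently. Ratios of saturated or dim spots on an array are in general compressed, and the files do not show which loci this concerns.

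From these values, the sign of the dye-swapped array was turned so that both arrays gave ΔrpaA over wild type, and the mean was taken as the value of a locus. The difference between the arrays times 0.5, called the swap deviation below, holds dye bias and array noise. It is only a rough guide to the technical error of that mean. A dye bias equal on both arrays cancels in the mean, and errors shared by both arrays do not enter the swap deviation. Both arrays hold the same 2 RNA pools, so they count as 1 replicate. There was 1 pool per strain. No locus or class was tested for a difference between the strains and no p-value is given, because neither biological variation between cultures nor variation between RNA preparations was measured. The number of arrays, 2, limits the precision, and so do dye bias, array noise and the unknown signal. Before the data were examined, a locus was set to count as higher or lower where both arrays lay at least 1 from 0 on the log2 scale, a 2-fold difference, on the same side. "Higher" and "lower" describe these 2 pools by that rule of size.

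The files identify loci by locus IDs and by a numeric database ID, and pair neither with gene names. None of these IDs (0 matches) occurred in the RefSeq table of 2785 genes that was available for names (assembly ASM3054490v1), which uses other locus tags. Gene symbols are therefore not given. Of the 29 gene lists fixed beforehand, 28 rest on symbols, products or the position of rpaA and were not analysed here. The list fixed as plasmid genes was defined by locus IDs that carry the letter B, an assignment the files do not state. Which locus ID is rpaA is not given in the sources used here, so the level of the disrupted gene, which would check the strain labels, was not analysed here. The rule for naming genes, fixed beforehand, took the disrupted gene, the clock and sigma factor genes, the 12 highest and 12 lowest loci, and members of the lists. It named a gene without a symbol by its locus ID and product. With neither symbols nor products the rule was cut to the 2 highest and the 2 lowest loci. That cut was a choice, since locus IDs were available, and the rest are given as counts and ranges. Locus IDs with the letter R and the open reading frames of pANS, a plasmid of this species, were taken as classes after the files were seen. What the letter R stands for is not stated in the files.

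The median of a class was placed among the medians of 10000 random lists with the same number of loci, matched on size alone because no signal level was used. The order of loci was taken from the locus numbers, since the files give no coordinates. Of the steps between consecutive locus numbers, 98.4% were also steps of 1 in the database IDs. For loci at consecutive numbers, the values were shuffled over the loci, 10000 times for counts of called loci and 1000 times for correlations. These are descriptions across loci, which are not independent replicates. The counting rule was tested on simulated arrays of 2723 loci with noise drawn from the observed swap deviations. It recovered 100% of 200 loci set 1.5 from 0 on the log2 scale and called 0 unchanged loci. That noise is technical and small beside the threshold, so the check shows only that the rule was computed as intended, and it does not cover differences between cultures. Loci set at the threshold itself were also simulated, but their recovery is not given here. The 100% therefore does not extend to loci near the threshold. Alternatives covered thresholds of 1.5-fold and 3-fold, a threshold on the mean, each array alone, centring, scaling the arrays to the same spread, leaving out loci whose arrays differed by over 1, and the authors' averaged table. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.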

Results

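Time-averaged transcript levels were compared between a ΔrpaA strain and its wild-type background in continuous light, to measure how loss of the clock-output regulator RpaA changed mean expression over a circadian cycle. The data comprise 2 arrays of the same 2 RNA pools with the dyes swapped, and 2723 loci had a listed value on both. They include 7 loci listed at exactly 0 on both arrays, which may not be measured ratios and are kept in the counts. Of the 2723 loci, 2611 carry a plain number in their locus ID, 50 carry the letter B and 53 carry the letter R. Another 8 are open reading frames of the plasmid pANS, and 1 has lost its locus name to a spreadsheet error. There was 1 RNA pool per strain, so the differences below have no replicate check, and the errors given are technical. They are given as the swap deviation, 0.5 times the difference between the arrays after the dye swap was turned.

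More loci were lower than higher in the ΔrpaA pool. On both arrays, 62 loci (2.28%) were at least 2-fold lower in ΔrpaA than in wild type and 12 loci (0.44%) were at least 2-fold higher. The lower loci also lay further from 0. Their median was -1.84 on the log2 scale, 3.59-fold below wild type, whereas the higher loci had a median of 1.35, 2.56-fold above wild type. On both arrays 24 loci were lower by at least 2 on the log2 scale, 13 by at least 3 and 5 by at least 4. By the same measure 1 locus was higher by at least 2, and 0 by at least 3. Which locus ID is rpaA is not given in the sources used here. The disrupted gene itself may therefore be among the lower loci, including those lowest in rank. The remaining 2649 loci (97.3%) met neither criterion, and 2449 loci (89.9%) had a mean within 0.5 of 0.

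The lowest locus was Synpcc7942_0834. Its log2 ratio was -6.31 with the ΔrpaA pool in Cy3 and -5.96 with that pool in Cy5, and the mean of -6.14 had a swap deviation of 0.18. This ratio corresponds to a 70.4-fold lower level in the ΔrpaA pool. For this and the other folds given here, the signal is unknown, so whether a channel lay near background was not tested. An error of that kind shared by both arrays does not enter the swap deviation. The loci with the preceding and the following number had means of 0.30 and 0.087, so neither met the 2-fold criterion. The next lowest locus, Synpcc7942_2336, was 27.3-fold lower, with a mean of -4.77 and a swap deviation of 0.013. The locus numbered just before it was also lower on both arrays, at -1.89 and -2.05, while the locus just after it had a mean of 0.062. The 10 loci that followed in rank had means between -4.66 and -3.11. The locus without a name was also among the lower loci, with -1.97 and -1.72 on the arrays, and was singled out only because its name is missing.

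The highest locus was Synpcc7942_2274, 4.22-fold higher in ΔrpaA, with log2 ratios of 1.92 and 2.23 and a mean of 2.08. Synpcc7942_0800 followed at 4.15-fold, with ratios of 2.00 and 2.10 and a mean of 2.05. The loci numbered just before and after Synpcc7942_2274 had means of 0.25 and 0.027, and those beside Synpcc7942_0800 had -0.31 and 0.31. The other 10 higher loci had means between 1.12 and 1.61. The authors' deposited table lists -6.14, -4.77, 2.08 and 2.05 for Synpcc7942_0834, Synpcc7942_2336, Synpcc7942_2274 and Synpcc7942_0800.

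**Figure D1:**
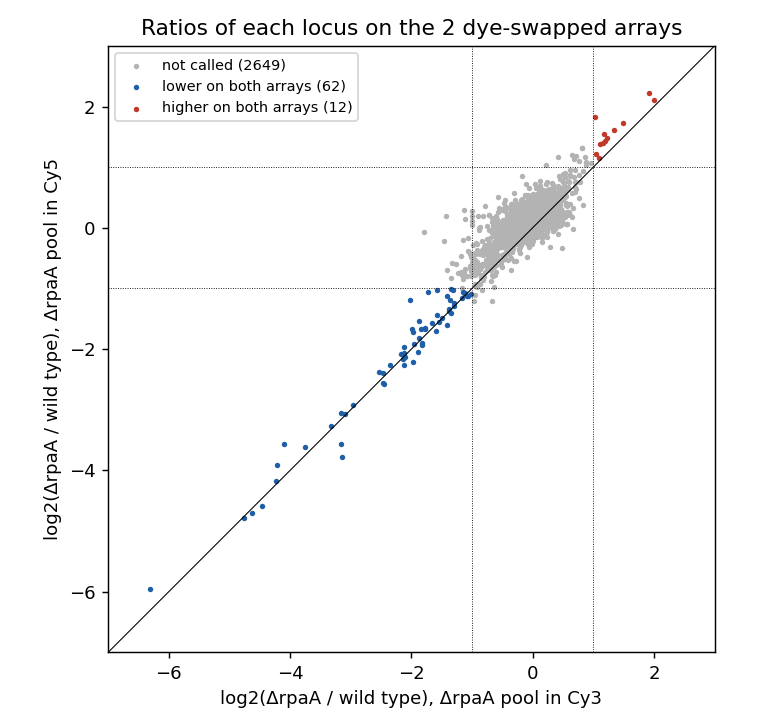
Each point is a locus, with its log2 ratio of ΔrpaA over wild type on the array with the ΔrpaA pool in Cy3 (x axis) and on the dye-swapped array (y axis). The solid line marks equal ratios and the dotted lines mark 2-fold differences. The 62 lower loci (blue) extend to -6.31 and -5.96, and the 12 higher loci (red) reach 2.00 on the x axis and 2.23 on the y axis.

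The swap deviation had an SD of 0.11 over the 2723 loci, and the 2-fold threshold is 8.97 times that SD. That multiple leaves out errors shared by both arrays and differences between cultures. It also overstates the margin, because the threshold applies to each array, whose own noise is larger than that of the swap deviation. The SD leaves out the median swap deviation of -0.086, and the largest absolute swap deviation over all loci was 0.86. Among the 74 called loci, which lie at least 1 from 0 by the rule that chose them, the largest absolute swap deviation was 0.41, a difference of 0.83 between the arrays. After the swap was turned, the ratios on the arrays correlated across loci with a Pearson r of 0.89 and a Spearman rho of 0.68. Among loci that met neither criterion r was 0.73 and rho was 0.66. Loci are not independent replicates, and these correlations describe array agreement only. The arrays gave opposite signs at 925 loci (34.0%). The signs were taken without centring, with medians of all loci of -0.039 and 0.12, so that offset may account for part of them. None of these loci had an absolute mean above 0.62. Opposite signs hold the absolute mean below the absolute swap deviation, so this bound does not measure agreement.

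The counts near the threshold differed between the arrays, and with 1 array per dye orientation dye and array cannot be told apart. The median ratio of all loci was -0.039 with the ΔrpaA pool in Cy3 and 0.12 with it in Cy5. With only the array that had ΔrpaA in Cy3, 95 loci were at least 2-fold lower and 12 were higher. With only the array that had ΔrpaA in Cy5, 66 were lower and 24 were higher, so lower loci made up 73.3% of those called instead of 83.8%. With a threshold of 1.5-fold on both arrays, 126 loci were lower and 36 were higher, and at 3-fold 37 were lower and 2 were higher.

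Loci that were lower in ΔrpaA often had consecutive numbers. Of the 61 lower loci with a 4-digit number, 27 had a lower locus at the preceding or following number. When the values were shuffled over the loci, the median of that count was 2 and the highest of 10000 shuffles gave 14. The 61 loci formed 46 runs of consecutive numbers, of which 34 held a single locus, 10 held a pair and 2 were longer, and the longest held 4 loci. None of the 12 higher loci (0) had a higher locus at a consecutive number, where the shuffles gave between 0 and 2 in their middle 95%. The shuffles had a median of 0, so this count cannot show whether higher loci cluster less than lower ones. It also rests on the rule that both arrays lie beyond 2-fold. Synpcc7942_0906, just after the higher locus Synpcc7942_0905, had ratios of 0.81 and 1.31 and a mean of 1.06.

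**Figure D2:**
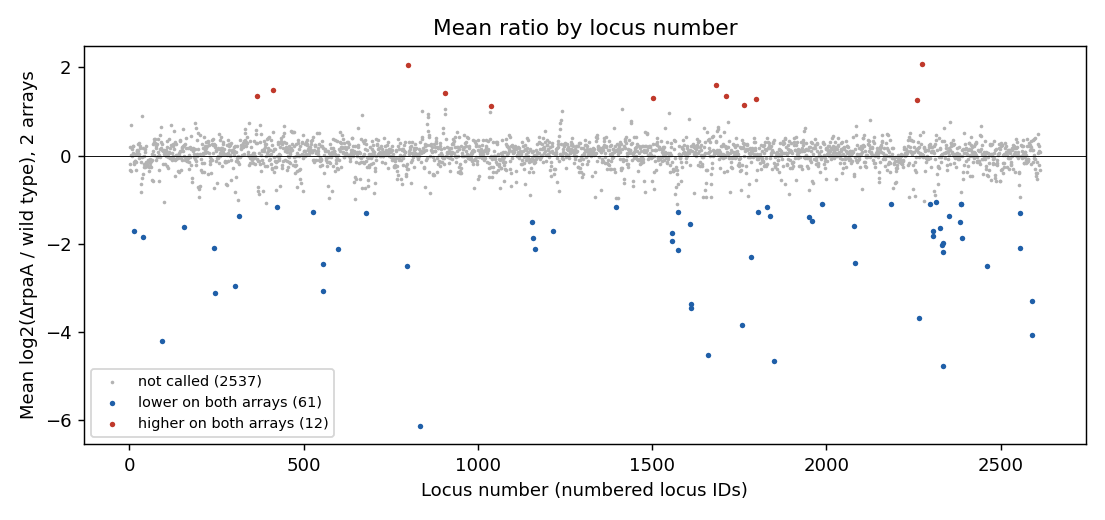
Each point is a locus with a 4-digit number, placed by that number (x axis) and by its mean log2 ratio of ΔrpaA over wild type on the arrays (y axis). The 61 lower loci (blue) lie along the whole range of numbers from 1 to 2613, with several at adjoining numbers. None of the 12 higher loci (red) adjoins another locus called higher.

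Locus IDs with the letter B, fixed beforehand as the list of plasmid genes, did not stand apart from other loci in their median. Their median was -0.00095 on the log2 scale, with an interquartile range from -0.046 to 0.078. That range was narrower than the one over all loci, from -0.12 to 0.18. That median lay at percentile 11.6 among random lists of 50 loci. None of them (0 of 50) met the 2-fold criterion in either direction, and 4 had a mean of -0.5 or lower. Of the 2611 loci with a plain number, 182 had such a mean. The 8 open reading frames of pANS had a median of 0.055, at percentile 55.4 among random lists of 8 loci. None of these (0 of 8) met the 2-fold criterion, and their means ran from -0.58 to 0.35. With 74 of all 2723 loci called, counts of 0 are unremarkable in classes this small.

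Locus IDs with the letter R had a median of -0.23, below the middle 95% of random lists of 53 loci, which ran from -0.028 to 0.11. Of the 53 R loci, 5 were listed at exactly 0 on both arrays, as were 2 numbered loci. Of the other 48 R loci, 43 had a mean below the median of all loci. None of the 53 (0) met the 2-fold criterion, which is unremarkable in a class of this size with 74 of all 2723 loci called. The arrays did not give the same value for this class. The R loci had a median of -0.57 with the ΔrpaA pool in Cy3 and of 0.11 with it in Cy5, where the median of all loci was 0.12. Of the 48 R loci not at 0, 45 lay below the median of all loci on the first array and 22 on the second. The ratios of the arrays differed by over 1 on the log2 scale at 14 loci, of which 13 were R loci.

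**Figure D3:**
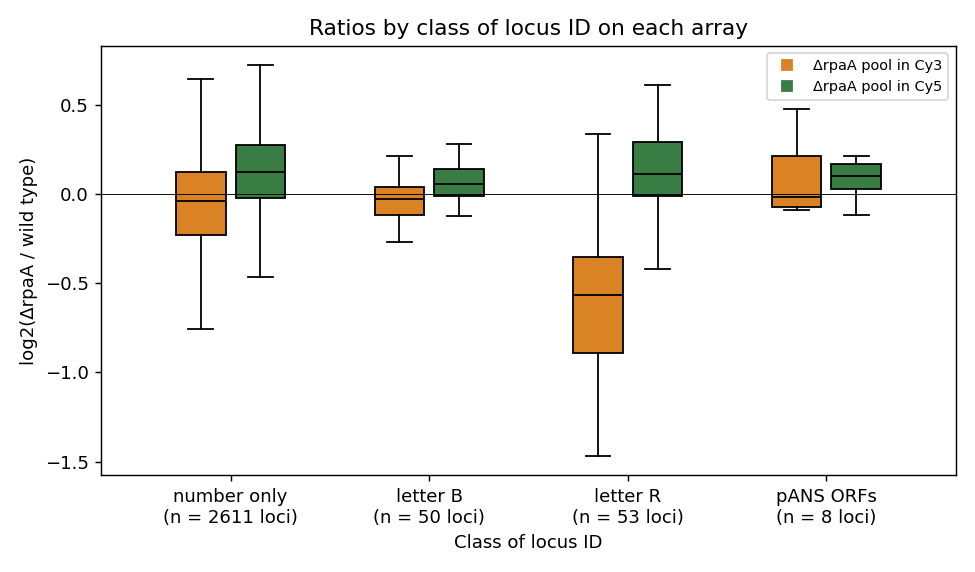
Boxes show the median and quartiles of the log2 ratio of ΔrpaA over wild type over the loci of each class of locus ID, with whiskers to the furthest value within 1.5 interquartile ranges and outlying points left out. Colours mark the arrays with the ΔrpaA pool in Cy3 and in Cy5. The R loci have a median of -0.57 on the first and 0.11 on the second, while the medians of the other classes lie between -0.036 and 0.12 on both.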

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

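The direction of the imbalance between lower and higher loci was the same under each alternative tried, with lower loci making up between 73.3% and 94.9% of those called. With a threshold of 1.5-fold on both arrays 36 loci were higher and 126 lower, and with 3-fold 2 were higher and 37 lower, as a looser or stricter threshold sets. With one array alone the higher loci numbered 12 to 24 and the lower loci 66 to 95, including the 12 and 62 called on both. The threshold on the mean gave 16 and 67 loci, and the authors' averaged table, whose rounding adds 1 lower locus, gave 16 and 68. Centring each array on its median gave 12 and 62, of which 12 and 61 were among those called without centring. Scaling the arrays to the same median absolute deviation gave 10 and 61. Leaving out the 14 loci whose arrays differ by over 1 removed 0 called loci. The median of the R loci, a class chosen after seeing the data, ran from -0.57 to 0.11 with one array alone, so its sign rests on the array with ΔrpaA in Cy3. It was -0.27 with centring, -0.15 without the 14 loci and -0.25 without loci at 0 on both arrays. Of the 39 alternative values for class medians and named loci, 33 moved by no more than 1 SD of the swap deviation, and the largest move was 0.34, at the R loci. Many of these moves were fixed in advance, so the count does not measure robustness. The authors' averages are the same means rounded, and centring shifts all loci alike. With one array alone, a named locus moves by its own swap deviation. The 14 loci left out hold no B or pANS locus. The level of rpaA and 28 gene lists were not computed under any setting, because the loci carry no gene names. No paired analysis was possible because the arrays share a single replicate number and hold the same pools. Signal over background is unknown here, so how far dim or saturated spots compress a ratio was not tested.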

Other observations

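The likeness of consecutive loci was not limited to the called ones. Across the 2606 pairs of consecutive locus numbers, the mean ratios correlated with a Spearman rho of 0.24, where 1000 shuffles gave between -0.038 and 0.039 in their middle 95%. Among pairs with both means within 2-fold of wild type rho was 0.23. It was 0.10 at a distance of 2 numbers and 0.0052 at a distance of 3. The medians of 10 equal stretches of locus numbers spanned 0.053 on the log2 scale, where 1000 shuffles had a median span of 0.047 and reached 0.090. Of the called loci, 41 of the 61 lower loci had locus number 1309 or above, the upper 50% of the numbers. Counted as runs, 29 of 46 (63.0%, exact binomial 95% interval 47.5 to 76.8%) began there, an interval that includes an even division.

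The tests of chance adjacency, of centring, of the dye effect on the counts and of a dye effect alone for the R loci, and the comparison of upper and lower locus numbers, were chosen after the results they concern had been seen. Chance adjacency does not account for the lower loci at consecutive numbers, since 27 had a lower neighbour and the highest of 10000 shuffles gave 14. A dye or array effect shared by consecutive loci is argued against by the correlation of one array with the other array at the next locus number, which was 0.19 with a highest shuffled value of 0.060, because turning the swap gives a dye effect opposite signs. The swap deviations of consecutive loci also correlated, with a rho of 0.15 where 1000 shuffles gave between -0.037 and 0.038 in their middle 95%, so the argument is only against such an effect as the whole cause. A candidate explanation is that consecutive loci are transcribed together and respond together to the loss of RpaA. Neither this nor cross-hybridization between similar neighbouring sequences was tested, because no strand, transcript or probe sequence was used here.

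Centring is argued against as the whole cause of the excess of lower over higher loci, because percentile 1 of the mean ratios lay 2.71 times as far from the median as percentile 99, a ratio that no shift of all loci alters. It was 2.60 and 2.62 on the arrays alone. The ratio of lower to higher loci was 2.75 in the orientation where it was smaller. Each array's counts include the 62 lower and 12 higher loci called on both, so this ratio largely restates theirs. Loci called on only 1 array differed by orientation. With ΔrpaA in Cy3 (95 lower and 12 higher in total) they were all lower. With ΔrpaA in Cy5 (66 lower and 24 higher in total) more were higher than lower. A dye or array effect can give such a reversal, so these counts do not decide on a dye effect. With each run of consecutive lower loci called on both arrays counted once, the ratio of lower to higher was still 3.83. Untested and open are loss of RpaA as an activator of more loci than it represses, and a difference between these particular cultures, since there was 1 pool per strain.

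The lower median of the R loci may be an array effect rather than a strain difference. Relative to the median of all loci, the class deviated by -0.53 on the array with ΔrpaA in Cy3 and by -0.0088 on the other, as an effect of one array predicts. A dye effect alone is argued against, because it would need a deviation of 0.53 on the second array and so a mean near 0, and the mean deviation was -0.27 (-0.34 to -0.18 in the middle 95% of 1000 resamples of the R loci, which covers the spread over loci only). The low mean ratios were spread over the class rather than held by a few extreme loci. The upper quartile of the class, -0.031, also lay below the median of all loci, 0.044. So did 90.6% of R loci, and 43 of 48 (89.6%) without the 5 listed at 0 on both arrays. This largely restates the low class median, which a few extreme loci hardly move. It also rests on 1 array, since with ΔrpaA in Cy5 only 22 of those 48 lay below that array's median. A real decrease combined with a dye effect of about equal size would give the same values, and with 1 array per orientation it stays open.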
